A study of Mus musculus with 18 samples.

How the data were processed

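The series holds bulk RNA-seq of mouse liver tumours (12 libraries) and 6 single-cell samples. The bulk libraries come from 2 tumour models. In the DEN+CCl4 model, per the labels, mice received the carcinogen N-nitrosodiethylamine (DEN, 1 mg/kg) at 14 days of age and the liver toxin carbon tetrachloride (CCl4, 0.2 ml/kg) from 8 weeks of age. In the N-Ras+AKT model, plasmids for an activated N-Ras and a myristoylated AKT (20 µg each) and the Sleeping Beauty transposase that inserts them (1.6 µg) were injected with a large volume into the tail vein, a route that brings DNA into hepatocytes. Each model has 3 control libraries and 3 libraries labelled Prom1 depletion, from mice in which tamoxifen (4 mg doses) activates a Cre recombinase made under the Prom1 promoter, which switches on diphtheria toxin A and kills the cells that express it. Tumours were taken 16 days (DEN+CCl4) or 6 days (N-Ras+AKT) after the last dose. Groups and replicate numbers were read from the sample titles. The groups share fewer than 2 replicate numbers, and no batch, sex or litter is given in the labels.

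Per the labels' protocols, RNA from frozen tissue was made into poly-A libraries with the KAPA mRNA HyperPrep kit and sequenced on a NovaSeq instrument. The values are counts per gene in whole numbers, not normalized, deposited by the authors as 1 table with a column per bulk library. Per the submitters' processing notes, STAR 2.7.3, RSEM 1.3.1, Cell Ranger 3.0.2 and the genome build mm10 were used in the series, with no role or order stated. The counts deposited by the authors may therefore be RSEM estimates rounded to whole numbers, in which reads shared by near-identical genes are split by a model. Values of the Mup, Serpinb9, Cyp2b, Cyp3a, Cyp4a, Sult and globin genes are uncertain for that reason. The annotation release, the strand setting and any filter are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. The table has 55335 genes under versioned Ensembl identifiers. Symbols, biotypes and positions were taken from GENCODE M21 on GRCm38, the assembly that mm10 names, by matching identifiers without version. Of these, 55154 matched, and the 181 that did not held 0.0064% of the counts. The 6 single-cell samples were not analysed here.

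Library totals ran from 31306617 to 48055812 counts. Library sizes were scaled with TMM factors (0.773 to 1.323), and genes with too few counts were removed with edgeR's filterByExpr, which left 17013 genes. All 12 libraries entered 1 fit of 4 group means with edgeR 4.0.16 (quasi-likelihood, robust, 8 residual degrees of freedom) in R 4.3.3. The common biological coefficient of variation was 0.238. The contrasts were Prom1 depletion against control in each model, the difference of these effects (N-Ras+AKT minus DEN+CCl4), and N-Ras+AKT control against DEN+CCl4 control. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The tests were of either direction. Standard errors (SE) of log2 fold changes are those implied by the quasi-likelihood F statistic. Levels are CPM, counts scaled by the TMM-adjusted library size, given as mean ± SD over 3 libraries.

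Gene lists for pathways and cell types (36 lists of 10 to 36 genes, 734 different genes, 27 of them in more than 1 list) were fixed before the data were examined, as were the groups, contrasts, alternatives and the rule for the genes named. Members were counted over all genes tested and again adjusted over the list alone. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, first with a preset correlation of 0.01 between genes and then with a correlation estimated for each list, and with fry. A camera p compares a list with the other genes. A fry p tests whether a list's genes move on balance in 1 direction, and its mixed p whether they change in either direction. List p-values were adjusted over the lists of 1 comparison. The lists were stem and progenitor markers, proliferation, mature hepatocyte function, pericentral and Wnt targets, periportal hepatocyte, cholangiocyte, stellate cell and fibroblast, endothelial, macrophage and Kupffer cell, T and NK cell, B and plasma cell and neutrophil markers, dendritic cell and antigen presentation, erythroid cells, other tissues, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPARa targets, bile acid synthesis and transport, xenobiotic metabolism, NRF2 targets, male-biased and female-biased hepatocyte genes, acute phase response, interferon response, inflammatory chemokines and NF-kB targets, p53 targets, unfolded protein and integrated stress response, glycolysis and hypoxia, YAP targets, Notch pathway, MAPK output, epithelial-mesenchymal transition, mitochondrially encoded genes, nuclear oxidative phosphorylation genes and ribosomal proteins.

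The rule for named genes took Prom1 first. Per depletion comparison it took the 12 higher and 12 lower genes with the largest fold change among those that passed, with a mean of at least 1 CPM in the model, all 3 depletion libraries on 1 side of all 3 control libraries, and a symbol that is not a clone, predicted gene or pseudogene. It also took up to 4 members per list that passed (those with the smallest adjusted p, or 2 members given as values where fewer passed), the 5 higher and 5 lower genes of the difference, the 10 higher and 10 lower genes between the control tumours, and Nras and Akt1. Other genes were chosen after their values were seen, most to name the members of a small count: Aldh1a1, Cd3e, Trem2, Cx3cr1, Vim, Axl, Il1a, Cxcl16, Fas, Ei24, Cyp3a16 and Alb after depletion, Mcm7, Pcna, Cldn3, Ngp, Dlk1, Ifit2, Cyp2f2, Cyp3a41a and Cyp17a1 between the control tumours, and Plk2, Amdhd2, CT010467.1, Ddx3y and Xist. Some genes that the rule takes are not reported here. For a group with a count of 0 in all libraries, folds were computed against a floor of 3 counts over the group. With 1 count, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

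Alternatives were DESeq2's size factors or upper-quartile factors in place of TMM, DESeq2 1.42.0 and limma-voom in place of edgeR, no filter or a mean of at least 1 CPM, only the 6 libraries compared, a fold above 2, 1 surrogate variable (sva 3.50.0), an estimated correlation for lists, and each library left out in turn. Single named genes were run with size factors, DESeq2, voom, only the 6 libraries and each library left out. One alternative was chosen after seeing the data, leaving out both depletion libraries that stand apart. Replicates were compared in pairs within each group. Chi-square over degrees of freedom was between 55.9 and 223.1, so no pair agreed within sampling noise, and no library was counted as a repeat of another. The labels do not say that each library is a different animal, so the p-values measure the spread between these tumour samples. The scripts were tested on simulated counts with the same design. Counts were drawn independently for each gene, and 100 genes per size of change were planted in each model, among genes with ample counts. No simulated library stood apart. In the data 23.7% of genes passed in N-Ras+AKT and some libraries stood apart, so the rates that follow need not hold for the data. For genes planted at a log2 change of 1 and 2, edgeR recovered 58% and 84% in the DEN+CCl4 comparison (4.05% of its calls false), 65% and 89% in the N-Ras+AKT comparison (6.1% false), and 32.5% and 72.5% for the difference (4.11% false).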

Results

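RNA was measured in mouse hepatocellular carcinomas, tumours of the liver, from 2 models, each with and without ablation of the cells that express Prom1. Prom1 codes for prominin-1 (CD133), a membrane protein used as a marker of progenitor-like cells in liver tumours. The 4 groups had 3 libraries each. Total counts were 36336745 to 43130284 in the DEN+CCl4 controls, 31306617 to 39840156 after depletion in that model, 37451706 to 48055812 in the N-Ras+AKT controls and 37258632 to 42197526 after depletion in that model. The strain label gives every bulk library the genotype with the Prom1 knock-in, while the design text names wild-type littermates as controls and also a vehicle. Whether a control lacked the knock-in, the tamoxifen or both is therefore not settled.

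Prom1 (ENSMUSG00000029086.15, chromosome 5, 43993620 to 44102032, minus strand, GRCm38) was lower in all 3 depletion libraries than in all 3 controls of each model. In the N-Ras+AKT model it fell by 2.90 on the log2 scale (SE 0.61, adjusted p = 0.00953), from 60.9 ± 16.5 to 8.16 ± 7.45 CPM (SD, n = 3). Its adjusted p lay between 5.47e-05 and 0.0373 over the 10 alternatives run for single genes, which were size factors, DESeq2, voom, the 6 libraries alone and each of them left out. In the DEN+CCl4 model the mean was 61.9 ± 14.0 CPM in controls and 31.03 ± 12.0 CPM after depletion (SD, n = 3). That log2 difference of −0.99 (SE 0.57, adjusted p = 0.381) did not pass the test. The difference of the effects between the models did not pass over all libraries (log2 difference −1.90, SE 0.81, adjusted p = 0.151). Its adjusted p lay between 0.0177 and 0.274 over 15 alternatives, and it passed only without N-Ras+AKT depletion 11 (log2 −2.94, adjusted p = 0.0177). A knock-in that removes 1 of 2 Prom1 alleles would by itself lower the transcript by 1 on the log2 scale. DEN+CCl4 depletion libraries 6, 9 and 10 had 17.45, 39.98 and 35.66 CPM. N-Ras+AKT depletion libraries 6, 11 and 17 had 5.807, 16.49 and 2.166 CPM.

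**Figure D1:**
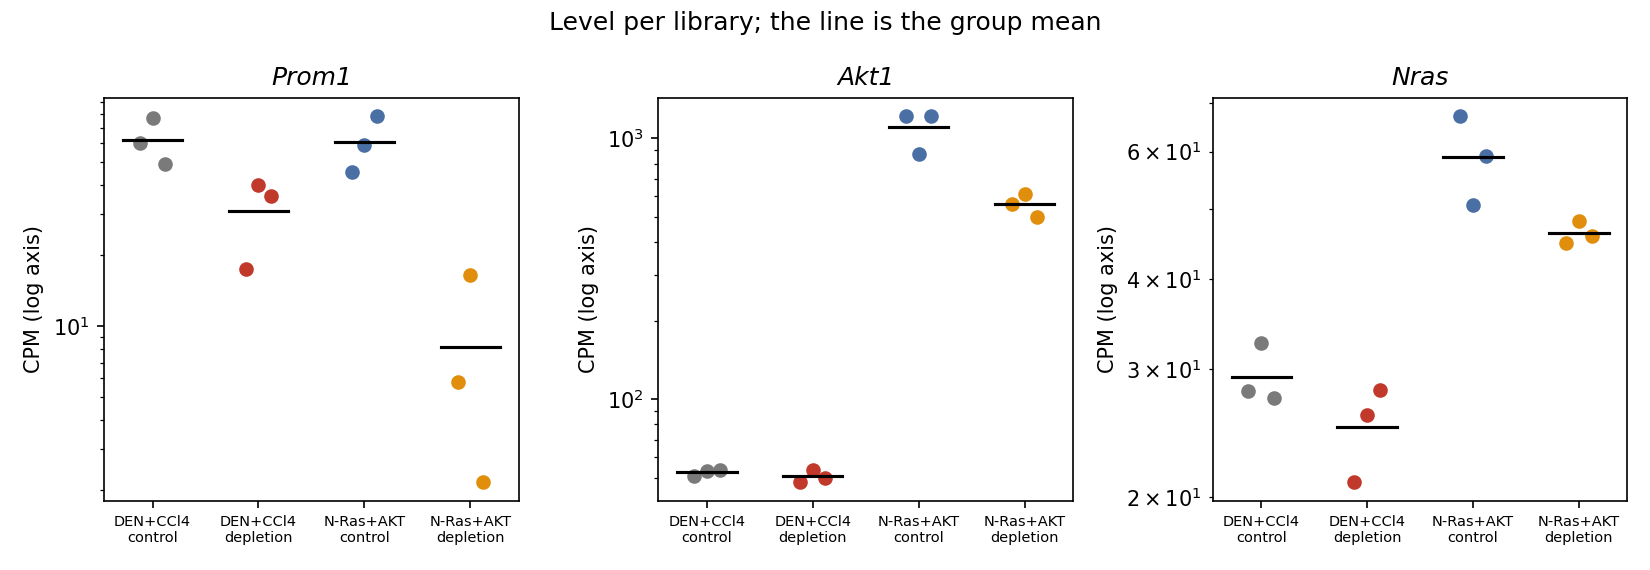
Level of Prom1, Akt1 and Nras in each of the 12 libraries, in CPM on a log axis, by model and treatment, with a line at the mean of each group of 3. Prom1 lies lower in all 3 depletion libraries than in the controls of the same model, and Akt1 is near 1100 CPM in N-Ras+AKT controls, 557 CPM after depletion and about 50 CPM in the DEN+CCl4 model.

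In the DEN+CCl4 model, a small set of inflammatory genes was higher in the Prom1 depletion libraries than in the controls. Tnfaip3, which codes for the NF-kB inhibitor A20, rose 4.10-fold (log2 2.03, SE 0.32, adjusted p = 0.0355), from 9.75 ± 3.07 to 40.0 ± 17.5 CPM (SD, n = 3). Cxcl1, a chemokine that attracts neutrophils, rose 3.16-fold, and Icam1, an adhesion molecule for leukocytes, rose 2.05-fold (adjusted p = 0.0433 and 0.0155). Cbr3, a carbonyl reductase, fell by 4.21 on the log2 scale (SE 0.55, adjusted p = 0.0195), from 21.5 ± 9.52 to 1.16 ± 0.161 CPM. Sult1c2, a sulfotransferase (chromosome 17, 53829637 to 53846339), fell by 2.06 (SE 0.21, adjusted p = 0.00479), from 7.48 ± 0.705 to 1.79 ± 0.365 CPM. Of these 5 calls, that of Sult1c2 alone was kept with each library left out. That of Tnfaip3 ended without control 7, control 8, depletion 6 or depletion 9 (adjusted p = 0.171, 0.122, 0.0576 and 0.0566), as did those of Cxcl1 (0.191, 0.144, 0.0934 and 0.0608) and Cbr3 (0.0825, 0.0776, 0.0948 and 0.107), and that of Icam1 without control 7, control 8 or depletion 9 (0.0825, 0.0776 and 0.0564).

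In all, 63 of 17013 genes passed the edgeR test, 19 higher and 44 lower, against 3186 at an unadjusted p under 0.05. Among the 63, all depletion libraries lay on 1 side of all controls, as they did for 27.5% of the genes tested (10% by chance). The other genes that rose most were Dusp8, a phosphatase of MAP kinases (log2 2.06), Fyb2 (1.81), Relb, an NF-kB subunit (1.49), Ccdc122 (1.20), the vasopressin receptor Avpr1a (1.14), Rnd2 (1.02), Pemt, which makes phosphatidylcholine (0.98), the iron transporter Slc11a2 (0.93) and Fam171b (0.90). Their adjusted p-values lay between 0.00963 and 0.0498. Among the lower genes were Serpina6, the corticosteroid-binding globulin (log2 −2.80), the imprinted gene Mest (−2.77), Klk1b4 (−2.41), the calcineurin regulator Rcan2 (−2.32), Cyp2b13 (−2.31), Adamtsl5 (−2.12), the interferon-induced GTPase Tgtp2 (−1.98), Drc1 (−1.79), Cys1 (−1.71) and Filip1 (−1.68), with adjusted p between 0.0155 and 0.045.

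The list of inflammatory chemokines and NF-kB targets had 5 of 21 measured members higher (Tnfaip3, Cxcl1, Relb, Icam1 and Nfkb2) and none lower. Adjusted over the list alone, 9 rose and 1 fell. Its median was 0.88 (camera adjusted p = 0.000529, adjusted p = 0.342 with an estimated correlation), or 0.55 without depletion 10. Neutrophil markers had a median of 0.71 with no member past the test over all genes or over the list alone (camera adjusted p = 0.00674, adjusted p = 0.414 with an estimated correlation). Mmp9, a gelatinase of neutrophils, had a log2 difference of 2.21 (adjusted p = 0.108) and S100a9 one of 0.89 (0.188). Acute phase genes had a median of 0.46, or 0.29 without depletion 6 (camera adjusted p = 8.11e-05, adjusted p = 0.414 with an estimated correlation), with none of 26 past the test over all genes and 5 higher adjusted over the list alone. Lbp, which binds bacterial lipopolysaccharide, had a log2 difference of 1.75 (adjusted p = 0.0876) and Orm1 one of 1.16 (0.0867). With 1 library left out, the NF-kB targets that passed, 5 over all libraries, were 0 without control 7, control 8 or depletion 9 and 1 without depletion 6.

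Interferon response genes had the smallest camera p. Of 29 measured, 2 fell, Tap1 and Psmb8, which act in antigen processing (log2 −0.99 and −1.01), and 19 fell adjusted over the list alone, with a median of −0.85 (camera adjusted p = 8.29e-11, adjusted p = 0.414 with an estimated correlation). Over all genes 0 interferon members passed without control 7, 8 or 13 or depletion 6 or 9, and 5 without depletion 10. Markers of several cell types had negative medians with no member past the test over all genes. Adjusted over the list alone, 14 of 18 endothelial markers fell (median −0.90, camera adjusted p = 7.34e-09), 11 of 14 dendritic cell and antigen presentation genes (−1.32, 1.41e-06), 11 of 15 B and plasma cell markers (−1.17, 1.77e-06), 5 of 17 T and NK cell markers (−1.46, 2.65e-05) and 6 of 6 erythroid genes (−3.01, 8.14e-06). With an estimated correlation, each of these 5 lists had an adjusted p of 0.414. Without depletion 10 the median of B and plasma cell markers was −2.49. Values of single members were −1.18 for the endothelial receptor Tie1 (adjusted p = 0.0537), −0.51 for the scavenger receptor Stab1 (0.0636), −1.97 for the T cell coreceptor Cd4 (0.0589), −1.90 for Cd3g (0.107), −1.68 for H2-Aa of the class II complex (0.0737), −2.82 for the chemokine receptor Ccr7 (0.0737), and −4.12 and −3.08 for the globins Hbb-bt and Hba-a1 (0.0696 and 0.0779). Cd4, Cd3g and Ccr7 had means under 1 CPM in all 4 groups. Macrophage and Kupffer cell markers had a median of 0.04 and a mean of −0.02 (camera adjusted p = 0.684).

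NRF2 targets had 1 of 16 lower, Gclc, which makes glutathione (log2 −1.23, adjusted p = 0.0313, but 0.171, 0.119, 0.0948 and 0.121 without control 7, control 8, depletion 6 or depletion 9), and 6 lower adjusted over the list alone (median −0.59, camera adjusted p = 0.00032, adjusted p = 0.414 with an estimated correlation). Further lists with a negative median were stellate cell and fibroblast markers (−0.74, camera adjusted p = 0.00104), Notch pathway (−0.81, 0.00232), epithelial-mesenchymal transition (−0.45, 0.00417), fatty acid synthesis (−0.50, 0.00661), cholangiocyte markers (−0.57, 0.00796), stem and progenitor markers (−0.67, 0.0207), male-biased hepatocyte genes (−0.85, 0.0225), p53 targets (−0.27, 0.0235) and MAPK output (−0.33, 0.037). In none of these 9 did a member pass over all genes. Several of them rested on single libraries. The stellate call ended without depletion 6 (median −0.39, camera adjusted p = 0.081), a library that lay at −2.05 against the controls while the others lay at −0.565 and −0.35. The stellate median was −0.47 without control 13 and −1.12 without depletion 10. The calls of fatty acid synthesis ended without control 8 (median −0.30, camera adjusted p = 0.0771), of p53 targets without control 13 or depletion 9 (0.0777 and 0.0808) and of MAPK output without control 7, control 13, depletion 6 or depletion 10 (0.0602, 0.0712, 0.0769 and 0.0622). Medians also moved for cholangiocyte markers, to −0.36 without depletion 6 and −1.12 without depletion 10, and for p53 targets, to −0.13 without depletion 6. Leaving out both depletion libraries that stand apart, here and in N-Ras+AKT, was chosen after seeing the data. It ended the calls of fatty acid synthesis (median −0.33, camera adjusted p = 0.0545) and MAPK output (0.0539) and kept that of stellate markers at a median of −0.38. Adjusted over the list alone, 7 p53 targets, 3 cholangiocyte markers, 3 epithelial-mesenchymal transition genes, 3 male-biased genes, 2 Notch genes and 2 stem and progenitor markers fell, and 1 stem and progenitor marker rose. Mup3, a male-biased urinary protein gene, had a log2 difference of −4.05 (adjusted p = 0.0566) and Selenbp2 one of −2.42 (0.0663). Ribosomal proteins (median 0.29, or 0.17 without depletion 6, camera adjusted p = 2.52e-06), mitochondrially encoded genes (0.35, 0.000263), nuclear oxidative phosphorylation genes (0.17, 0.00032) and unfolded protein and integrated stress response genes (0.15, 0.0127) were called higher as lists with no member past either adjustment. With an estimated correlation, these 4 lists and the 9 before them had adjusted p from 0.414 to 0.6. The mitochondrially encoded mt-Nd1 and mt-Co2 had log2 differences of 0.61 and 0.53 (adjusted p = 0.194 and 0.197).

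Not called in this model were proliferation (median 0.17, camera adjusted p = 0.109), mature hepatocyte function (0.15, 0.434), pericentral and Wnt targets (0.06, 0.723), periportal hepatocyte (0.15, 0.071), cholesterol synthesis (0.05, 0.265), fatty acid oxidation and PPARa targets (−0.03, 0.48), bile acid synthesis and transport (0.22, 0.329), xenobiotic metabolism (0.16, 0.715), glycolysis and hypoxia (0.07, 0.438), YAP targets (−0.14, 0.426), genes of other tissues (0.13, 0.684) and female-biased hepatocyte genes (0.72, 0.167), of which Cyp2b13 fell. Adjusted over the list alone, 3 xenobiotic metabolism genes rose and 7 fell (fry mixed adjusted p = 0.0016), 2 mature hepatocyte genes rose and 3 fell (0.00353), 2 female-biased genes rose and 1 fell (0.0054), 2 pericentral genes rose and 1 fell (0.0355), 1 periportal gene rose and 1 fell (0.127), 1 fatty acid oxidation gene fell (0.104), and none of the other 7 lists not called had such a member. For proliferation and xenobiotic metabolism the camera direction was down although median and mean were above 0. With 1 library left out, proliferation was called higher without depletion 6 (median 0.65, camera adjusted p = 0.000387) and lower without depletion 9 (−0.835, 1.12e-06), depletion 10 (0.205, 0.0435) or control 7 (0.04, 0.0438), so its direction is not settled. Cholesterol synthesis was called higher without control 7 (0.13, 0.0375) or control 8 (0.32, 0.00162) and lower without control 13 (−0.25, 0.0202), which also gave calls to female-biased (1.435, 0.0331) and periportal genes (0.28, 0.0147). Camera called 23 of 36 lists, 7 higher and 16 lower, and 0 with an estimated correlation (adjusted p from 0.342 to 0.893, 3 with an unadjusted p under 0.05), while fry called 4 and its mixed test 19. The number of genes rested on single libraries: it was 2 without control 8, 3 without control 7, 6 without depletion 9, 10 without depletion 6, 30 without control 13 and 465 without depletion 10, while DESeq2 called 1043 genes and a fit of the 6 libraries alone 13. Of the 28 named genes that passed, Sult1c2 alone passed with each library left out in turn, and 27 calls each ended without control 7 (adjusted p up to 0.198) or control 8 (0.15), 24 without depletion 9 (0.125), 22 without depletion 6 (0.141) and 13 without control 13 (0.104).

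Depletion library 6 of this model stood apart on the third principal component (11.5% of the variance), at −84.1 against −13.8 and −0.1 in the other depletion libraries and 35.8 to 39.4 in the controls. It also had the lowest Prom1 level of its group (17.45 CPM), as N-Ras+AKT depletion 17 had of its own (2.166 CPM). Leaving both out thus removes the libraries with the least Prom1, and whether they stand apart for that reason was not tested. The proliferation list of DEN+CCl4 depletion 6 lay 2.68 below the controls on the log2 scale, against 0.02 and 1.11 above them in the others. Without this library and N-Ras+AKT depletion 17, both left out after seeing the data, proliferation was called higher (median 0.65, camera adjusted p = 0.000868, against 0.17 and 0.109 over all libraries) and its difference between the models lower (median −1.08, camera adjusted p = 0.00124, against −0.61 and 0.968). That difference was called lower without DEN+CCl4 depletion 6 alone (median −1.093, camera adjusted p = 0.000731). It was called higher without DEN+CCl4 depletion 9 (median 0.277, camera adjusted p = 0.0248), so its direction is not settled either. Ribosomal RNA of 1 annotated gene (CT010467.1) took 12.39, 7.32 and 3.02% of the counts in the controls and 3.42, 2.3 and 5.06% after depletion.

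**Figure D2:**
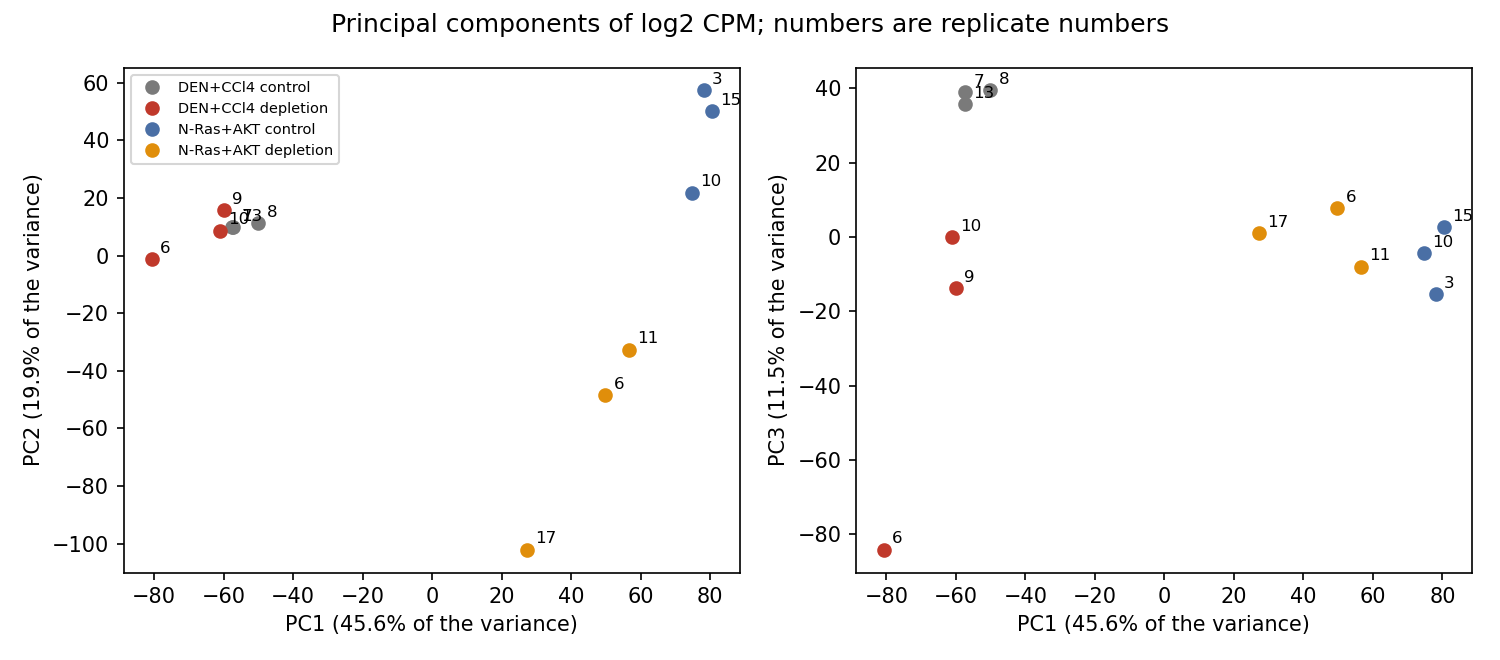
First 3 principal components of log2 CPM, each point 1 of 12 libraries with its replicate number, coloured by model and treatment. PC1 (45.6% of the variance) separates the models, PC2 (19.9%) the N-Ras+AKT depletion libraries, with library 17 at −102.1, and PC3 (11.5%) the DEN+CCl4 depletion libraries, with library 6 at −84.1.

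In the N-Ras+AKT model, the depletion libraries had higher list medians for differentiated hepatocytes, lymphocytes and macrophages and lower ones for bile duct epithelium and MAP kinase output, and a lower level of Akt1 (log2 −0.98). None of these lists kept its call with an estimated correlation (adjusted p from 0.305), and depletion library 17 stood apart from the other 2. Cyp8b1, a sterol hydroxylase of bile acid synthesis (chromosome 9, 121914356 to 121916305), rose 36.8-fold (log2 5.20, SE 0.80, adjusted p = 0.00381), from 2.80 ± 1.88 to 102 ± 57.8 CPM (SD, n = 3). Glul, the glutamine synthetase of hepatocytes around the central vein (chromosome 1, 153899944 to 153909723), rose 6.21-fold (log2 2.63, SE 0.36, adjusted p = 0.00334), from 83.8 ± 43.5 to 520 ± 133 CPM. Sox9, a transcription factor of bile duct cells (chromosome 11, 112782224 to 112787760), fell by 2.51 on the log2 scale (SE 0.43, adjusted p = 0.00452), from 62.4 ± 4.64 to 10.9 ± 6.40 CPM. Cftr, the chloride channel of bile duct epithelium, fell by 4.48 (SE 0.88, adjusted p = 0.00733).

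Of 17013 genes, 4027 (23.7%) passed, 2186 higher and 1841 lower. The genes that rose most were Sult2a8 (log2 5.71, adjusted p = 0.00451), the major urinary protein genes Mup7, Mup10, Mup18, Mup11, Mup15 and Mup17 (4.69 to 5.67), the sulfotransferases Sult5a1 (4.91) and Sult3a1 (4.55), the fatty acid elongase Elovl3 (4.85) and the transcription factor Rfx4 (4.71). Members of the Mup and Sult families share reads, so their separate values are uncertain. Sult2a8 went from 1.20 ± 0.772 to 62.4 ± 59.6 CPM. Besides Cftr, genes that fell most included the engulfment receptor Megf10 (log2 −5.23), Diras2 (−4.96), Gal3st2c (−4.88), the kainate receptor Grik3 (−4.67), Wdr72 (−4.37), the imprinted Zim1 (−4.36), the transcription factor Tbx1 (−4.31), the placental growth factor Pgf (−4.28), Pthlh and the potassium channel Kcnma1 (−3.90). Their adjusted p-values lay between 0.00334 and 0.0403. Some of these sizes rested on single libraries. Without control 3 that of Pgf was −1.63 and that of Pthlh −2.32 (adjusted p = 0.201 and 0.154), without depletion 17 that of Mup7 was 2.87 (0.121), and without depletion 11 those of Gal3st2c and Zim1 were −7.72 and −6.97.

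Mature hepatocyte function had 21 of 32 measured members higher and none lower, also adjusted over the list alone, with a median of 1.14 (camera adjusted p = 1.99e-09, adjusted p = 0.305 with an estimated correlation). Among them were Hpd of tyrosine breakdown (log2 2.92), the alcohol-oxidising Cyp2e1 (3.06) and the bile acid importer Slc10a1 (2.26). Albumin (Alb), the gene with the most counts, had a log2 difference of −0.21 (adjusted p = 0.506). Pericentral and Wnt targets rose in 15 of 19, 16 adjusted over the list alone (median 1.99, camera adjusted p = 1.06e-09, adjusted p = 0.305 with an estimated correlation), with Glul, Lgr5 (2.60) and the Wnt inhibitor Notum (adjusted p = 0.00334). Periportal hepatocyte genes rose in 6 of 14, with 7 higher and 1 lower adjusted over the list alone (median 0.68, camera adjusted p = 0.0163, adjusted p = 0.413 with an estimated correlation), including Pigr (2.17) and Hal (2.53). This call ended without control 15 (median 0.54, camera adjusted p = 0.0529). Without depletion 17 the median was 0.41, and without both depletion libraries that stand apart it was 0.41 with 4 members higher (camera adjusted p = 0.0363). Of the mature hepatocyte genes, 13 were higher without control 15.

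Lists of bile acid, fatty acid, xenobiotic and mitochondrial metabolism had higher members, while glycolysis and cholesterol synthesis are given further on. Bile acid synthesis and transport had 16 of 18 members higher, also adjusted over the list alone (median 1.75, camera adjusted p = 1.08e-09, adjusted p = 0.305 with an estimated correlation), among them Slc27a5 (log2 1.88), Hsd3b7 (1.76) and the phospholipid exporter Abcb4 (1.27). Fatty acid oxidation and PPARa targets rose in 17 of 24, 21 adjusted over the list alone (median 0.91, camera adjusted p = 4.12e-09, 0.305 as adjusted p with an estimated correlation), with Cpt2, which brings fatty acids into mitochondria (1.03). Fatty acid synthesis rose in 9 of 20, 12 adjusted over the list alone (median 0.97, or 0.645 without depletion 6, camera adjusted p = 0.000334, adjusted p = 0.37 with an estimated correlation), with Fasn (1.96), Me1 (2.04) and the carbohydrate-sensing factor Mlxipl (1.40). Xenobiotic metabolism rose in 14 of 25, 17 adjusted over the list alone (median 1.26, or 1.96 without control 10, camera adjusted p = 2.27e-08, adjusted p = 0.314 with an estimated correlation), with Ugt1a1 (1.91) and the receptor Nr1i3 (2.35). NRF2 targets rose in 4 of 16 under both adjustments, Gclm, Me1, Ugdh and the ferritin light chain Ftl1 (0.99), with a median of 0.42 (camera adjusted p = 0.00365, adjusted p = 0.403 with an estimated correlation), a call that ended without control 3 (camera adjusted p = 0.0507). Mitochondrially encoded genes rose in 12 of 13, all 13 adjusted over the list alone (median 0.78, camera adjusted p = 1.51e-07, adjusted p = 0.334 with an estimated correlation), such as mt-Co2 (0.99) and mt-Nd3 (0.87). Nuclear oxidative phosphorylation genes rose in 13 of 29, 16 adjusted over the list alone (median 0.31, camera adjusted p = 1.56e-06, adjusted p = 0.37 with an estimated correlation), such as Ndufb9 (0.52) and Sdhb (0.66). With 1 library left out fewer members passed, and by most for the following. Fatty acid oxidation had 10 higher without control 3, 9 without control 15 and 7 without depletion 17, and xenobiotic metabolism 7 without control 15 and 9 without depletion 17. Mitochondrially encoded genes had 3 without control 3, control 15 or depletion 17 and 6 without depletion 11, and nuclear oxidative phosphorylation 7 without control 3 and 6 without depletion 17. NRF2 targets had 2 without control 3, control 15, depletion 6 or depletion 17, but 7 without control 10.

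Genes with a sex bias in liver rose in the male-biased and in the female-biased list. The Y-linked gene Ddx3y had 57.52 to 92.44 CPM over all 12 libraries. Xist, which female cells express, had 0.09253 to 1.408 CPM. These values argue against a difference in sex between the groups. Male-biased genes had 8 of 18 higher and Cspg5 lower (9 and 1 adjusted over the list alone, median 1.47, camera adjusted p = 0.000758), with Susd4 (log2 3.57) and Cyp7b1 (3.55). Female-biased genes had 8 of 21 higher and Cyp3a16 lower, also adjusted over the list alone (median 0.35, camera adjusted p = 0.00879), with Cyp2b13 (4.04) and Acot3 (2.54). Both lists had an adjusted p of 0.37 with an estimated correlation. The male-biased median was 0.93 without depletion 17. Without both depletion libraries that stand apart it was 0.93 too, with 3 members higher and 1 lower, and the female-biased median was 0.655 with 8 higher. The female-biased call ended without depletion 11 (camera adjusted p = 0.0926), and its median was 0.61 without control 3, 0.65 without control 10, 0.58 without depletion 6 and 0.65 without depletion 17. Male-biased genes higher were 2 without control 3 or depletion 17, 3 without control 15 and 4 without depletion 6.

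Cholangiocyte markers fell in 13 of 19, 16 adjusted over the list alone, with a median of −2.08 (camera adjusted p = 2.27e-08, adjusted p = 0.305 with an estimated correlation). Sox9 and Cftr were among them. MAPK output genes fell in 13 of 19, 16 adjusted over the list alone (median −0.98, camera adjusted p = 4.46e-07, adjusted p = 0.305 with an estimated correlation), including the feedback inhibitors Spry2 (log2 −2.02) and Spred1 (−0.92) and the factor Etv5 (−1.26). Notch pathway genes fell in 10 of 17, 11 adjusted over the list alone (median −1.19, camera adjusted p = 6.8e-06, adjusted p = 0.305 with an estimated correlation), with the target Hes1 (−1.64) and the receptor Notch2 (−0.60). Stem and progenitor markers fell in 9 of 23, with Prom1, Sox9 and Sox4 (−1.40), and rose in 2, Lgr5 and Aldh1a1. Adjusted over that list alone, 13 fell and 2 rose (median −1.59, camera adjusted p = 0.000146, adjusted p = 0.37 with an estimated correlation). YAP targets fell in 8 of 18, with Arhgef17 (−1.77), and rose in 2, Axl and Nt5e (1.71), or 11 and 2 adjusted over the list alone (median −0.86, camera adjusted p = 0.00526, adjusted p = 0.37 with an estimated correlation). Glycolysis and hypoxia genes fell in 9 of 24, 13 adjusted over the list alone (median −0.85, camera adjusted p = 0.0024, adjusted p = 0.498 with an estimated correlation), with the carbonic anhydrase Car9 (−2.71) and the glucose transporter Slc2a1 (−1.98). Epithelial-mesenchymal transition genes fell in 4 of 17 (among them Vim, Mmp14 at −0.95 and the epithelial cadherin Cdh1 at −1.24) and Tgfbi rose, or 5 and 1 adjusted over the list alone (median −0.56, camera adjusted p = 0.0298, adjusted p = 0.413 with an estimated correlation). Ribosomal proteins had a median of −0.33 with Rps6 lower over all genes and none adjusted over the list alone (camera adjusted p = 9.1e-05, adjusted p = 0.495 with an estimated correlation). The call of epithelial-mesenchymal transition genes ended without depletion 11 (camera adjusted p = 0.0695), and their median was −0.36 without control 3. Without control 3 the median of glycolysis and hypoxia genes was −0.31, and that of ribosomal proteins was −0.20 without control 3 or depletion 17. Without control 3, members lower were 8 for cholangiocyte markers, 8 for MAPK output, 6 for Notch, 5 for YAP targets and 3 for glycolysis. Without depletion 6 they were 8 for cholangiocyte markers, 6 for Notch, 5 for YAP targets and 3 for glycolysis, without depletion 17 they were 6 for Notch and 2 for glycolysis, and without control 15 they were 4 for YAP targets. Ribosomal proteins had 8 lower without depletion 11. The log2 value of Slc2a1 was −1.295 without control 3.

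Lymphocyte, macrophage and dendritic cell lists had positive medians, whereas the neutrophil list had a negative one and was not called. T and NK cell markers rose in 5 of 17, 8 adjusted over the list alone (median 1.37, camera adjusted p = 3.53e-05, adjusted p = 0.334 with an estimated correlation). These were Cd3e, Cd3g (log2 1.37), Cd8a (1.70), Gzma (2.37) and Nkg7 (1.94). The calls of Cd3g, Cd8a, Gzma and Nkg7 ended without control 3, control 15, depletion 6 or depletion 17, with adjusted p of up to 0.145, 0.129, 0.107 and 0.128, and that of Cd3g also without control 10 (0.0891). B and plasma cell markers rose in 8 of 15, 12 adjusted over the list alone (median 1.78, camera adjusted p = 0.000133, adjusted p = 0.37 with an estimated correlation), with the immunoglobulin heavy chain Ighm (2.87) and the B cell receptor component Cd79a (2.56). Macrophage and Kupffer cell markers rose in 13 of 22, with C1qa (0.77), Folr2 (2.03) and the Kupffer cell receptor Timd4 (2.65), while Trem2 and Cx3cr1 fell. Adjusted over that list alone, 14 rose and 3 fell (median 0.78, camera adjusted p = 0.000475, adjusted p = 0.37 with an estimated correlation). Dendritic cell and antigen presentation genes rose in 3 of 14, Clec9a (1.70), Batf3 (1.90) and H2-DMa, and in 7 adjusted over the list alone (median 1.05, camera adjusted p = 0.00127, adjusted p = 0.37 with an estimated correlation). Interferon response genes rose in 13 of 29 under both adjustments (median 0.53, camera adjusted p = 9.1e-05, adjusted p = 0.413 with an estimated correlation), with the GTPases Igtp (1.39), Gbp3 (1.96) and Gbp2 (1.63). Fewer members of these lists passed with 1 library left out. T and NK cell markers had 0 without control 3, control 15, depletion 6 or depletion 17. B and plasma cell markers had 2 without control 3, 5 without control 10, 3 without control 15, 4 without depletion 6 and 1 without depletion 17. Interferon response had 8 without control 10 or depletion 6, 6 without control 15 and 5 without depletion 17, and macrophage markers had 8 without depletion 17. The fall of Trem2 and Cx3cr1 did not pass without control 3, 10 or 15 or depletion 17. The log2 value of Gzma was 3.801 without control 10.

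The list of inflammatory chemokines and NF-kB targets had 5 of 21 lower, Cxcl16, Relb (log2 −1.31), Vcam1 (−1.02), Nfkb2 (−0.89) and Icam1 (−0.63), and Il1a higher (8 lower and 2 higher adjusted over the list alone), and was not called (median −0.53, camera adjusted p = 0.057). Endothelial markers had 6 of 18 higher, such as the sinusoidal genes Stab2 (1.26), Oit3 (1.31) and Clec4g (1.76), and Vwf of larger vessels lower (adjusted p = 0.00474), also adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.323). Acute phase genes had 5 of 26 higher, with Saa3 (2.38), and 3 lower, with the interleukin-1 antagonist Il1rn (−1.72), also adjusted over the list alone (median 0.42, camera adjusted p = 0.152). p53 targets had 2 of 20 higher, Fas and Ei24, and 8 lower, with Btg2 (−1.62), also adjusted over the list alone (median −0.18, camera adjusted p = 0.0588). None of the 36 proliferation genes passed under either adjustment (median −0.49, camera adjusted p = 0.205). Not called were also stellate cell and fibroblast markers (1 of 24 higher, Dcn, median −0.42, camera adjusted p = 0.178), neutrophil markers (1 of 11 lower, Il1r2 at −1.66, median −0.36, 0.164), erythroid genes (0 of 6, −0.72, 0.489), genes of other tissues (2 of 6 lower, Msln and Upk3b, −1.297, 0.164), cholesterol synthesis (2 of 24 higher, with Ebp, −0.13, 0.702) and unfolded protein and integrated stress response (1 of 22 higher, Edem1, −0.03, 0.947, camera direction up). Adjusted over the list alone, the genes of other tissues kept 2 and the remaining 5 lists none. With 1 library left out, NF-kB targets were called lower without control 3, depletion 6 or depletion 17 (camera adjusted p = 0.0372, 0.0236 and 0.0457), neutrophil markers without control 15 or depletion 6 (0.0188 and 0.0274), genes of other tissues without control 15 (0.0234), stellate markers without depletion 6 (0.00407), and p53 targets (0.037) and proliferation (0.00349) without control 3. Acute phase genes were called higher without control 3 (0.0319). Without both depletion libraries that stand apart, NF-kB targets were called lower (camera adjusted p = 0.0378). Endothelial markers had 2 higher without control 3, 3 without depletion 6 and 1 without control 15 or depletion 17. Acute phase genes had 1 higher without control 3 or 15, 3 without control 10 or depletion 11 and 2 without depletion 17, where Saa3 was 1.55. NF-kB targets had 3 lower without depletion 17, and p53 targets 5 lower without control 3, control 15, depletion 6 or depletion 17.

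**Figure D3:**
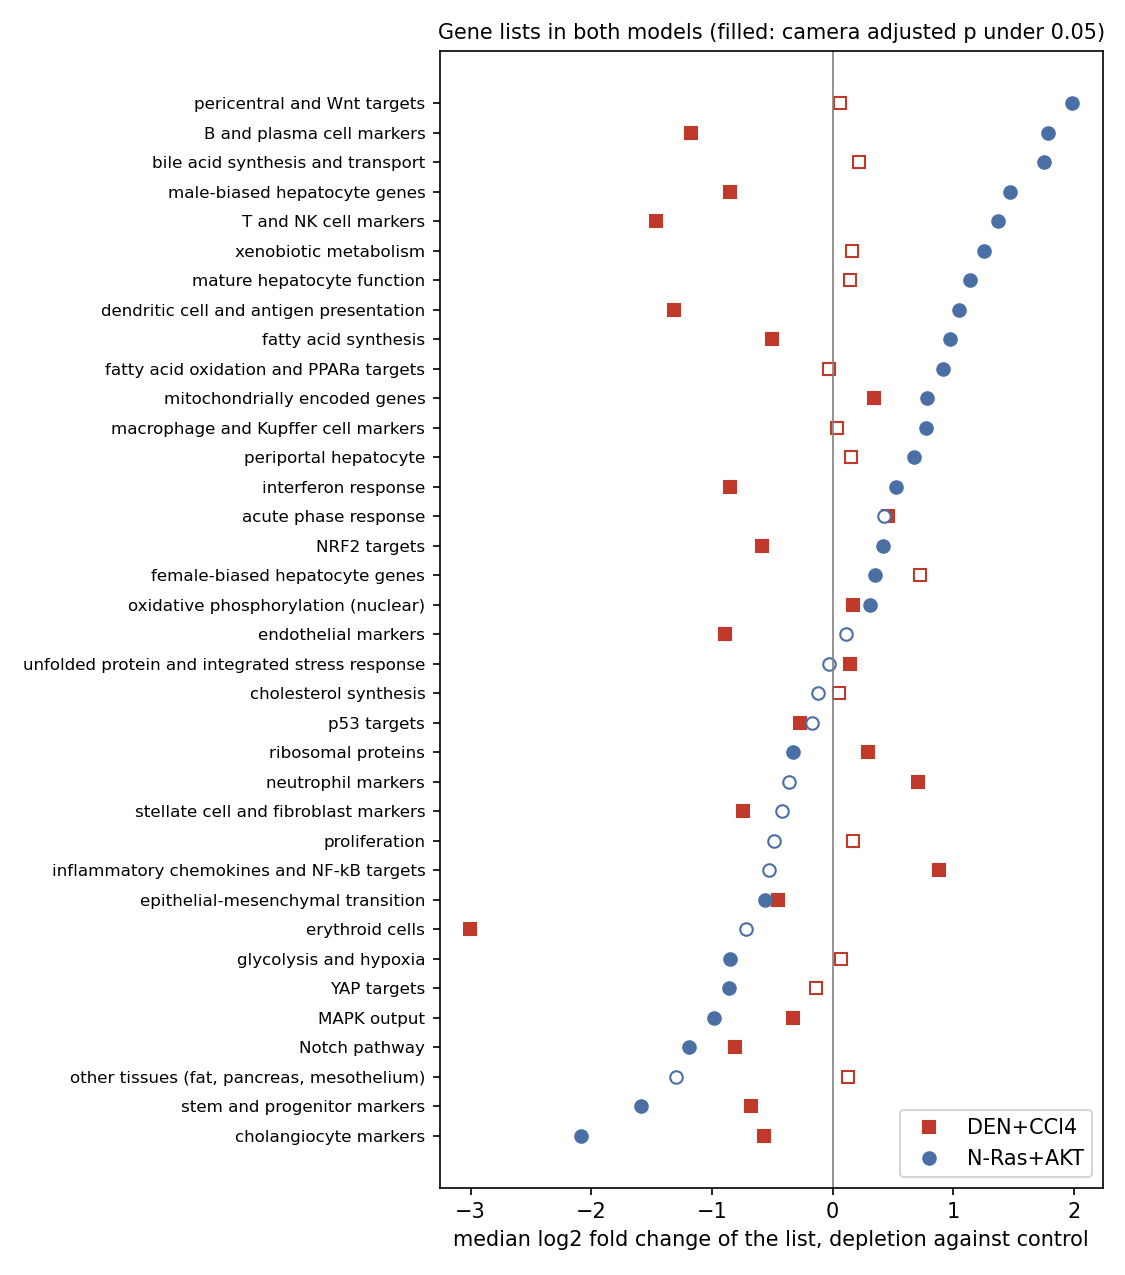
Median log2 fold change of each of the 36 gene lists after Prom1 depletion, in the DEN+CCl4 model (squares) and the N-Ras+AKT model (circles), filled where camera with a preset correlation gave an adjusted p under 0.05. Lymphoid, antigen presentation, male-biased and interferon lists lie below 0 in the first model and above 0 in the second; no list kept its call with an estimated correlation.

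Camera called 25 of the 36 lists in the N-Ras+AKT model, 17 higher and 8 lower, and 0 with an estimated correlation (adjusted p from 0.305 to 0.967, 3 with an unadjusted p under 0.05), while fry called 25 and its mixed test 30. Akt1 (chromosome 12, 112653821 to 112674884), whose counts can include those of the injected plasmid, fell by 0.98 on the log2 scale (SE 0.15, adjusted p = 0.00341), from 1100 ± 196 to 557 ± 56.4 CPM (SD, n = 3). Nras (chromosome 3, 103058285 to 103067914) had 58.97 ± 8.23 CPM in controls and 46.3 ± 1.71 CPM after depletion (log2 −0.35, SE 0.13, adjusted p = 0.072). The number of genes was 1768 without depletion 17, the library at −102.1 on the second principal component, 2225 without control 15 and 2257 without control 3. Of the 90 named genes that passed, 73 passed with each library left out in turn, and besides the T and NK genes above the calls of Cd79a, Clec4g, Diras2, Elovl3, Il1r2, Mup7, Mup15, Mup17, Oit3, Pgf, Pthlh, Stab2 and Vcam1 ended for at least 1 library. These and the T and NK calls make 15 lost without depletion 17 (adjusted p up to 0.145), 12 each without control 3 (0.201) and control 15 (0.112), 6 without depletion 6 (0.108), and 2 each without control 10 (0.143) and depletion 11 (0.103).

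The difference of the depletion effects between the models was then tested gene by gene, since a gene that passes in only 1 model need not differ between them. Tumours were taken 16 days after the last dose in DEN+CCl4 and 6 days after it in N-Ras+AKT. Model, cohort and time after tamoxifen thus go together, and this test cannot separate them. Whether the Prom1 fall differed was not settled. NF-kB genes were among those that differed. The depletion effect in N-Ras+AKT minus that in DEN+CCl4 was −2.85 for Tnfaip3 (SE 0.44, adjusted p = 0.00824), −2.80 for Relb (SE 0.38, adjusted p = 0.00595), −1.77 for Nfkb2 and −1.67 for Icam1. It was 3.16 for Gbp3 (SE 0.39, adjusted p = 0.00475), 2.07 for Igtp, 2.72 for Cd4, 3.97 for Ighm, 3.03 for Glul and 4.53 for Cyp7a1, the first enzyme of bile acid synthesis. For Peg3, an imprinted gene, it was −4.58 (SE 0.71, adjusted p = 0.00926).

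In total 1970 genes passed this test, 1357 with a higher and 613 with a lower effect in the N-Ras+AKT model. The largest fitted differences were those of Mup10 (log2 13.21), Mup11 (8.85), A4gnt (8.15), Sult2a8 (7.72) and Mup22 (7.69), and of Arg2 (−7.26), the estrogen sulfotransferase Sult1e1 (−6.36), Tbx1 (−6.09), Kcnma1 (−5.03) and Rgs7bp (−4.63). Mup10 and A4gnt had no count in the DEN+CCl4 depletion libraries, so their fitted values are no measure of size. They were at least 19.1-fold and 2.59-fold lower after depletion in that model, against a floor of 3 counts over the group. The mean of Arg2 after depletion there, 15.9 ± 23.8 CPM (SD, n = 3), had an SD above the mean, and its difference was −4.40 without DEN+CCl4 depletion 6. Camera called 23 lists, 17 with a higher and 6 with a lower effect in N-Ras+AKT, and 0 with an estimated correlation (adjusted p from 0.325 to 0.994, 4 with an unadjusted p under 0.05). The interferon list had 17 of 29 members higher (20 adjusted over the list alone, median 1.55, camera adjusted p = 9.65e-11). B and plasma cell markers had 10 of 15 higher (13 adjusted over the list alone, median 3.30, camera adjusted p = 8.29e-08; 6 higher without DEN+CCl4 control 8 or depletion 9, 5 without N-Ras+AKT control 3, control 15 or depletion 17), and NF-kB targets 6 of 21 lower and Il1a higher (8 and 1 adjusted over the list alone, median −0.71, or −1.097 without DEN+CCl4 control 7, camera adjusted p = 0.000633). The number of genes was 895 without DEN+CCl4 control 7, 1130 without control 8, 1181 without control 13 and 986 without depletion 9 of that model, and 1176, 1060, 1232 and 939 without N-Ras+AKT control 3, control 15, depletion 6 and depletion 17. The call of Akt1 ended without DEN+CCl4 control 7 or depletion 9 (adjusted p = 0.0594 and 0.0555), that of Kcnma1 without DEN+CCl4 control 7 or 8 (0.0574 and 0.0557), that of Mup10 without DEN+CCl4 control 7 (0.0531), and that of Arg2 without any 1 of DEN+CCl4 controls 7, 8 and 13, N-Ras+AKT controls 3 and 15 and depletion 6 and 17 (0.052 to 0.0712).

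Across all genes tested, the log2 fold changes of the 2 depletion comparisons, which share no library, had a Spearman correlation of 0.017 and a Pearson correlation of 0.026, where genes are not independent replicates. With 1 library left out the Spearman value ran from −0.035 (without DEN+CCl4 depletion 6) to 0.073 (without DEN+CCl4 depletion 9), so its sign is not settled. Of the N-Ras+AKT calls, 51% had the same sign in DEN+CCl4. The time after the last dose differed between the 2 comparisons, so a low correlation need not reflect the tumour model. Passing and higher in both was 1 gene, Rnd2, where independent lists give 2.44, and passing and lower in both were 3, Plk2, Amdhd2 and Drc1, where independent lists give 4.76. Another 5 genes, Relb, Slc11a2, Nfkb2, Icam1 and Fam171b, were higher in DEN+CCl4 and lower in N-Ras+AKT (2.06 by chance), and 8, among them Serpina6, Cyp2b13, Rcan2 and Tgtp2, were the reverse (5.65 by chance).

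The control tumours of the models were compared to describe them without depletion. N-Ras+AKT tumours had higher transcripts of progenitor and bile duct cells and of glycolysis, and lower transcripts of hepatocyte function and cholesterol synthesis. As lists, none of these was called by camera with an estimated correlation (smallest adjusted p = 0.666). Cd24a, a surface marker of progenitor cells, was higher by 4.81 on the log2 scale (SE 0.64, adjusted p = 0.000341), at 144 ± 26.6 against 5.12 ± 1.23 CPM (SD, n = 3). Akt1 was higher by 4.39 (SE 0.17, adjusted p = 1.94e-07) and Nras by 1.01 (SE 0.13, adjusted p = 0.000189), while Prom1 had a log2 difference of −0.02 (adjusted p = 0.98). Gldn was lower by −10.23 (SE 0.49, adjusted p = 2.81e-06), at 0.133 ± 0.106 against 171 ± 3.30 CPM.

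Of 17013 genes, 6901 passed, 3538 higher and 3363 lower in N-Ras+AKT. Of the named genes that were higher, 6 had no count in the DEN+CCl4 controls. Against a floor of 3 counts over the group, Serpinb9e was at least 569-fold higher, Gal3st2c at least 254-fold, Rasgrf1 at least 139-fold, Zim1 at least 105-fold, Serpinb9d at least 81.4-fold and Serpina5 at least 78.8-fold. Serpinb9f, Megf10 and Plekhd1 had 1 count there, which gives ratios of 1170 (95% counting interval 209 to 46000), 826 (148 to 32600) and 483 (86.7 to 19100). Cyp4a12a, a male-specific cytochrome, was higher by 8.46. Prom2, the paralog of Prom1, had no count in the N-Ras+AKT controls and was at least 1300-fold lower. Also lower were Cyp2b13 (log2 −8.47), Tff3 (−7.56), the basement membrane collagens Col4a3 (−7.19) and Col4a4 (−5.98), Mpped1 (−7.12), Wfdc15b (−6.54), Ipcef1 (−6.15) and the 5-lipoxygenase Alox5 (−5.91).

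None of the lists kept its call with an estimated correlation (smallest adjusted p = 0.666). Mature hepatocyte genes were lower in 23 of 32 and higher in 1 (25 and 1 adjusted over the list alone, median −1.22, camera adjusted p = 1.59e-07), with Apoa1 (−1.92), Alb (−1.60) and the hepatocyte factor Hnf4a (−1.22). Cholesterol synthesis was lower in 17 of 24 (19 adjusted over the list alone, median −0.96, camera adjusted p = 3.88e-06), with Mvk (−1.92). Endothelial markers were lower in 11 of 18 (13 adjusted over the list alone, median −1.12, 5.88e-06), with Stab2 (−2.57) and Oit3 (−2.77), and B and plasma cell markers in 7 of 15 (10 adjusted over the list alone, median −1.89, 0.000694), with Igkc (−3.92) and Jchain (−4.15). Glycolysis and hypoxia genes were higher in 18 of 24, also adjusted over the list alone (median 1.301, 8.05e-06), with Eno1 (1.56) and Hk2 (2.47). Ribosomal proteins were higher in 24 of 30 (28 adjusted over the list alone, median 0.57, 3.88e-06), such as Rplp1 (0.76) and Rps19 (0.93). Cholangiocyte markers were higher in 14 of 19 and Cldn3 lower, also adjusted over the list alone (median 2.09, 0.000694), with Cftr (6.30), and stem and progenitor markers in 13 of 23, with Sox4 (3.32), and lower in 3, Lgr5, Dlk1 and Anpep (16 and 3 adjusted over the list alone, median 2.09, 0.00329). Neutrophil markers were higher in 8 of 11 and Ngp lower (9 and 1 adjusted over the list alone, median 2.22, 0.00173), with S100a9 (2.23) and Il1r2 (4.62). Of 36 proliferation genes 2, Mcm7 and Pcna, were higher, also adjusted over the list alone (median 1.22, 0.0315). The proliferation call ended without DEN+CCl4 control 7 or 13 (camera adjusted p = 0.0752 and 0.0553) or N-Ras+AKT control 10 or 15 (0.075 and 0.232, with a median of 0.69 without 15). Ribosomal proteins had 11 higher without DEN+CCl4 control 7, 14 without control 13 and 12 without N-Ras+AKT control 3.

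Also called were NF-kB targets (12 of 21 higher and 2 lower, median 0.92, camera adjusted p = 0.0152) and erythroid genes (5 of 6 higher, 2.36, 0.0315). Lower as lists were interferon response (13 of 29 lower and Ifit2 higher, median −0.57, 0.00216), mitochondrially encoded genes (7 of 13 lower, −0.62, 0.00247), periportal hepatocyte (8 of 14 lower and Cyp2f2 higher, −1.72, 0.00329), female-biased genes (9 of 21 lower and 2 higher, Cyp3a41a and Cyp17a1, −1.27, 0.00571) and bile acid genes (8 of 18 lower, −0.85, 0.0152). The erythroid call ended without DEN+CCl4 control 8 or N-Ras+AKT control 3 (camera adjusted p = 0.0551 and 0.0717) and the bile acid call without N-Ras+AKT control 3 (median −0.495, camera adjusted p = 0.0717), while the female-biased median was −0.51 without DEN+CCl4 control 13. Interferon genes lower were 8 without DEN+CCl4 control 8 and 7 without N-Ras+AKT control 10 or 15. Mitochondrially encoded genes lower were 2 without DEN+CCl4 control 7 or N-Ras+AKT control 15 and 3 without DEN+CCl4 control 13 or N-Ras+AKT control 3. Erythroid genes higher were 3 without DEN+CCl4 control 7 or 8 or N-Ras+AKT control 3. Camera called 17 of the 36 lists, 8 higher and 9 lower, and 0 with an estimated correlation (adjusted p from 0.666 to 0.983, 1 with an unadjusted p under 0.05), while fry called 18 and its mixed test 33. Median and mean differed in sign for stellate cell and fibroblast markers, other tissues, fatty acid oxidation, stress response and epithelial-mesenchymal transition. Model, cohort, age and time after tamoxifen go together, so this comparison cannot separate them.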

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

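The tests weighed in this part, the splits of the samples included, were chosen after the results were seen. The verdict on the first cause weighed turned: an earlier form of its test, which looked only at genes already called lower and found 9 cholangiocyte, 3 MAPK output and 3 Notch genes beyond Akt1, spoke against that cause although 335 of all genes (18.2% of the lower calls, against 69.2, 23.1 and 30% in these lists) lay beyond Akt1 too, and it was replaced after its result was seen. By contrast, the test of the difference between the models was fixed before the data were examined. What brought the results below here is a difference between groups: the effect of Prom1 depletion differed between the 2 tumour models in the edgeR test, for 1970 genes, for 92 of the 136 genes named and for 23 lists by camera. Of all 17013 genes tested, 11.6% passed. Many named genes were chosen for passing in a comparison, the difference included, so a higher share among them follows from that choice. Values are log2 differences, the effect in N-Ras+AKT minus that in DEN+CCl4. Model, cohort and time after the last tamoxifen dose go together, so these differences cannot be ascribed to the model alone.

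List medians of this difference were above 0 for T and NK cell markers (2.72), B and plasma cell markers (3.30), dendritic cell and antigen presentation genes (2.255), macrophage and Kupffer cell markers (0.925), endothelial markers (0.85), erythroid genes (2.44) and interferon response genes (1.55). They were also above 0 for mature hepatocyte function (0.73), pericentral and Wnt targets (1.77), male-biased genes (2.52), fatty acid synthesis (1.45), fatty acid oxidation (1.11), bile acid genes (1.37), xenobiotic metabolism (1.24), NRF2 targets (1.16), mitochondrially encoded genes (0.455) and nuclear oxidative phosphorylation genes (0.19). Medians below 0 were those of cholangiocyte markers (−1.01), neutrophil markers (−1.31), inflammatory chemokines and NF-kB targets (−0.71), glycolysis and hypoxia genes (−0.61), MAPK output (−0.74) and ribosomal proteins (−0.65). With an estimated correlation none of the 23 list calls was kept (adjusted p from 0.325). With 1 library left out, the call of nuclear oxidative phosphorylation ended without DEN+CCl4 control 7, depletion 6 or depletion 9 or N-Ras+AKT control 15, depletion 11 or depletion 17 (camera adjusted p = 0.0838, 0.0672, 0.0536, 0.265, 0.164 and 0.0606). In N-Ras+AKT, leaving out control 3 ended that of glycolysis and hypoxia (0.0647, median −0.11), control 10 that of erythroid genes (0.0519) and control 15 that of mitochondrially encoded genes (0.0525, median 0.29). Medians also moved for cholangiocyte markers (−1.67 without N-Ras+AKT depletion 11, −0.65 without depletion 17), MAPK output (−0.48 without N-Ras+AKT depletion 17) and NF-kB targets (−1.097 without DEN+CCl4 control 7). Lists that gained a call for at least 1 library left out were Notch, YAP targets, stem and progenitor markers, proliferation, cholesterol synthesis, periportal, stellate and other tissues.

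Among immune genes, the difference was above 0 for the lymphocyte genes Cd4 (2.72), Cd3g (3.27), Cd8a (3.485), Gzma (3.83), Nkg7 (3.44), Ighm (3.97) and Cd79a (4.50). Antigen presentation, dendritic cell and migration genes were H2-Aa (2.64), Ccr7 (3.52), Clec9a (1.61) and Batf3 (2.15), and macrophage genes C1qa (0.77), Folr2 (2.28) and Timd4 (2.47). Genes induced by interferon were Tgtp2 (3.04), Tap1 (1.05), Psmb8 (1.19), Igtp (2.07), Gbp3 (3.16) and Gbp2 (2.48). Of the 21 NF-kB targets 6 passed lower and 1 higher, Il1a (1.72), and 5 had a value above 0. The NF-kB and inflammatory genes named that lay below 0 were Tnfaip3 (−2.85), Cxcl1 (−2.42), Relb (−2.80), Icam1 (−1.665), Nfkb2 (−1.77) and Il1rn (−1.36), while the acute phase gene Saa3 lay above (2.96). Endothelial genes were Stab1 (0.71), Stab2 (2.15), Oit3 (2.36) and Clec4g (2.23) above 0 and Vwf (−1.51) below.

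Of hepatocyte and zonation genes, 11 of 32 mature hepatocyte, 11 of 19 pericentral and 3 of 14 periportal genes passed higher and 1 periportal gene lower, and the periportal list was not called (camera adjusted p = 0.245). Without N-Ras+AKT depletion 6 the periportal list was called higher (median 0.562 against 0.267, camera adjusted p = 0.0347). Those named were Hpd (2.69), Slc10a1 (1.575), Cyp2e1 (2.76), Lgr5 (2.36), Notum (2.17), Glul (3.03), Pigr (2.02) and Hal (2.66). Sex-biased genes of liver were Mup3 (4.05), Mup10 (13.215), Mup11 (8.85), Mup22 (7.69), Selenbp2 (3.61), Susd4 (5.07), Cyp7b1 (3.36), Cyp2b13 (6.35) and Acot3 (2.76), where Mup10 had no count after depletion in DEN+CCl4. Bile acid genes were Cyp7a1 (4.53), Cyp8b1 (6.68), Slc27a5 (1.555), Hsd3b7 (1.84) and Abcb4 (1.035), and genes of lipid metabolism Mlxipl (1.435), Me1 (2.57), Fasn (2.51), Cpt2 (1.07) and Pemt (−1.02). For iron and glutathione genes the values were Ftl1 (1.40), Gclc (1.39) and Slc11a2 (−1.265).

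Further named genes below 0 were Akt1 (−0.93), Spry2 (−1.61), Etv5 (−1.15), Spred1 (−0.995), Dusp8 (−2.12), Sox9 (−2.55), Btg2 (−1.54), Slc2a1 (−2.14), Tbx1 (−6.09) and Kcnma1 (−5.03), while the YAP target Nt5e lay above (1.64). Also below 0 were Fyb2 (−2.195), Ccdc122 (−1.12), Fam171b (−1.39), Arg2 (−7.26), Sult1e1 (−6.355), Rgs7bp (−4.63) and Peg3 (−4.58). Those above 0 were Cbr3 (5.31), Serpina6 (6.42), Klk1b4 (2.65), Rcan2 (3.34), Adamtsl5 (2.19), Sult1c2 (1.82), Cys1 (1.09), Filip1 (1.54), Sult2a8 (7.72), Sult5a1 (5.34), Rfx4 (4.69) and A4gnt (8.15), and A4gnt had no count after depletion in DEN+CCl4.

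The first pattern weighed is the fall of cholangiocyte, MAPK output and Notch lists, with higher hepatocyte lists, after depletion in N-Ras+AKT, where Akt1 fell by 0.98 too. With an even loss, a lower share of transgene-bearing cells as the whole cause would let no transcript fall clearly further than Akt1. Beyond Akt1 and 2 of its standard errors, by a one-sided test adjusted over the members, lay 2 of 19 cholangiocyte markers (Sctr and Cftr), 0 of 19 MAPK output genes, 0 of 17 Notch genes and, adjusted over all, 0 of 17013 genes (5, 2, 1 and 218 at an unadjusted p under 0.05), short of the 3 set as the limit, so with so few beyond it this cause cannot be told apart from a change in particular cells. Depletion library 17 alone as the cause is argued against, since without it 8 of 8 lists kept their camera call with the preset correlation, at 72.6 to 97.2% of their median, although fewer members passed, such as 7 fatty acid oxidation genes (17 with it), 9 xenobiotic (14) and 6 Notch genes (10). With an estimated correlation none of these 8 lists is called over all libraries (adjusted p from 0.305), and no biological explanation was tested.

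The second pattern is the lower endothelial, lymphoid, antigen presentation, interferon and erythroid lists after depletion in DEN+CCl4. Fewer cells of all types other than hepatocytes, as the whole cause, would lower macrophage and endothelial markers alike, but the macrophage median lay above the endothelial one by 0.936 (SE 0.219) over the 3 depletion libraries, from 0.665 to 1.37, against −0.138 to 0.094 in the controls. A pair picked with its medians known cannot test this cause, and a gain of macrophages stays open. Depletion library 6 alone is argued against for these 6 lists only, since without it 6 of 6 lists kept their camera call with the preset correlation, at 68.5 to 86.9% of their median, and Tap1 and Psmb8 stayed at −0.96 and −0.85 (from −0.99 and −1.01), past the test no longer (adjusted p = 0.0948 and 0.129), although each list had an adjusted p of 0.414 with an estimated correlation over all libraries. The 6 lists were chosen after the results were seen. Stellate markers and MAPK output, lower in the same comparison but not among them, lost their calls without this library (camera adjusted p = 0.081 and 0.0769). Less blood in the tissue or fewer vessels and lymphocytes are candidate explanations that no test here separates.

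The third pattern is the lower Prom1 transcript in the depletion libraries. If the controls were wild type, loss of 1 allele to the knock-in would lower Prom1 by 1 on the log2 scale. In N-Ras+AKT the fall lay 3.11 standard errors beyond that, which argues against allele loss as the whole cause. In DEN+CCl4 it lay −0.0083 standard errors beyond it, so allele loss and loss of cells cannot be told apart there, because the labels leave the genotype of the controls open. Regrowth of Prom1-expressing cells between the last dose and the collection was not tested.

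Regrouping the libraries gave the following. In DEN+CCl4, 1 of 10 splits of the 6 libraries, the real one, called as many genes (63, the next highest 4), in N-Ras+AKT 1 of 10 (4027, the next highest 0), and between the control tumours 1 of 10 (6901, the next highest 0), by the edgeR test. With 10 splits, a share under 0.05 cannot be reached. For the difference between the models, 2 of 60 splits drawn from 200 called as many genes as the real one (1970), the other with 2029 and the next highest with 540. The one with 2029 swaps control and depletion in N-Ras+AKT and so tests the sum of the 2 effects. Most splits also break up the depletion effect of N-Ras+AKT, so they decide nothing about the difference.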

How the results depend on the processing

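The alternatives were fixed before the data were examined, apart from leaving out both depletion libraries that stand apart, which was chosen after seeing the data. For the DEN+CCl4 comparison (63 genes), DESeq2 called 1043, no filter on low counts 171, 1 surrogate variable 331, a fold above 2 38 and the 6 libraries alone 13. Leaving out 1 library gave 2 (without control 8) to 465 (without depletion 10), and leaving out both libraries that stand apart gave 26. DESeq2 and the surrogate variable kept all 63 of its genes, the 6 libraries alone 8. The N-Ras+AKT comparison (4027) had 2626 genes with its 6 libraries alone, 1986 at a fold above 2, 1768 (without depletion 17) to 4126 (without control 10) with 1 library left out, and 2429 without both libraries. The difference between the models (1970) had 895 (without DEN+CCl4 control 7) to 2326 (without N-Ras+AKT control 10), and 844 without both libraries. The control tumours (6901) had 3204 at a fold above 2. A fold limit can only lower a count. Fits with 1 library fewer called fewer or more genes depending on the library left out, and why these and the other counts changed was not tested.

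Lists called by camera (23 in DEN+CCl4, 25 in N-Ras+AKT, 23 for the difference, 17 between controls) were 0 with an estimated correlation in DEN+CCl4, 0 in N-Ras+AKT, 0 for the difference and 0 between controls. The correlation of both effects (0.017) was 0.047 over genes called in at least 1 comparison, and −0.035 (without DEN+CCl4 depletion 6) to 0.073 (without DEN+CCl4 depletion 9) with 1 library left out. The Prom1 difference between the control tumours (−0.02) ran from −0.246 to 0.161 with 1 library left out, being 0.161 without DEN+CCl4 control 8 and 0.152 without N-Ras+AKT control 3. With upper-quartile factors the median log2 value of all genes was −0.10 for the difference (−0.03 with TMM) and 0.12 between controls (0.04). The share of higher genes among those called went from 51.3 to 58.4% between controls, from 68.9 to 60.1% for the difference and from 54.3 to 49.4% in N-Ras+AKT (1998 higher and 2044 lower). Size factors, voom and a mean of at least 1 CPM kept all 4 counts within 1.5 times. Of the results, each a named gene in a comparison, DESeq2 kept the direction and side of the threshold of 188, gave 11 a call and ended 3. For voom these were 186, 3 and 14, and the 6 libraries alone kept 149 and ended 28. Counted again for each library left out they were 1175, 11 and 174, with 2 reversed, the Prom1 values above. List calls that ended with a mean of at least 1 CPM were MAPK output and T and NK cells in DEN+CCl4, T and NK cells in N-Ras+AKT, oxidative phosphorylation for the difference and NF-kB between controls. Leaving out 1 library ended those of MAPK output, fatty acid synthesis, p53 and stellate markers in DEN+CCl4, NRF2, periportal, epithelial-mesenchymal and female-biased genes in N-Ras+AKT, oxidative phosphorylation, glycolysis, erythroid and mitochondrially encoded genes for the difference, and proliferation, erythroid and bile acid genes between controls, with the libraries named in the results. Without both libraries those of fatty acid synthesis (0.0545) and MAPK output (0.0539) in DEN+CCl4 and oxidative phosphorylation for the difference (camera adjusted p = 0.0926) ended. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.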

Other observations

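Mitochondrially encoded genes took a larger share of the counts after depletion in both models, 8.1, 7.89 and 8.24% against 5.69, 5.63 and 6.06% in DEN+CCl4 and 7.79, 9.77 and 9.22% against 5.89, 7.02 and 4.86% in N-Ras+AKT. The annotated ribosomal RNA gene CT010467.1 took 1.16, 1.63 and 3.05% in N-Ras+AKT controls and 1.77, 1.13 and 0.59% after depletion. Albumin held between 5.02 and 15.54% of the counts of a library. Stellate cell and fibroblast markers of DEN+CCl4 depletion library 6 lay at a median of −2.05 against the controls.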
